A study of Mus musculus with 6 samples.

How the data were processed

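Total RNA was sequenced from mouse embryonic stem cells whose Ezh2 alleles are floxed, 3 libraries from untreated cells and 3 from cells given 4-hydroxytamoxifen. Per the labels' protocols, the drug was given at 800 nM for 96 h to delete Ezh2, and RNA was taken 4 days after treatment. Ribosomal RNA was depleted with Ribo-Zero Gold and directional Illumina libraries were made. The deposited table holds a normalized signal for each of 22933 Ensembl genes and 6 libraries. The submitters' processing notes name TopHat2, bedtools and DESeq2 without versions, and the build mm9. The labels give no annotation, strand setting or counting rule, and whether overlapping genes and near-identical copies share reads is not stated. All 6 columns were matched to libraries by the genotype and replicate number in their names.

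The deposited values are not reads divided by a single factor per library. Each of the 100305 values above 0 equals 9.73 × k × (m + 0.1) / (k + 0.1), where k and m are whole numbers, with a largest relative misfit of 5.07e-15. The test had been planned for reads divided by 1 factor per library, and the planned limma test of log2 values was kept for this form. The sorted values of m differ between libraries by at most 4. The number k was taken as the read count of the gene, and k is called recovered reads below. Exactly 1 solution existed for 98.8% of the values, and of the 1189 others 1083 were settled by the gene's other libraries and 106 by the ratio of m to k nearest 1. On simulated values the same solver returned the reads of 100.0% of 17354 values. The ratio m/k rose with GC content (Spearman rho across genes 0.257 to 0.523 in the 6 libraries) and fell with transcript length (-0.452 to -0.407). These correlations run across genes, which are not independent replicates. A gene with 1 read could carry a deposited value from near 0 up to 2416 in the library where that limit was lowest and 3071 in the one where it was highest.

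Values were compared as log2(value + 1) with limma 3.58.1 in R 4.3.3, using moderated tests with an expression trend, for 17427 genes with a mean value of at least 10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are tamoxifen minus untreated on the log2(value + 1) scale, where the added 1 shrinks changes of genes with low values. For genes under 10 reads on average, changes came out too large in the simulated data described below. Their median absolute log2 fold change was 1.34 for 2-fold and 2.64 for 4-fold changes. Where every library of a group was at 0, a lower bound was computed against a floor of 3 counts over that group, from recovered reads over each group's total reads. No bound was given where the other group had 3 reads or fewer. Such bounds cover the counting error of the group at 0 only, since the reads of the other group enter as counted. Symbols came from GENCODE vM21 on GRCm38 by Ensembl identifier, for 20273 genes, and coordinates are given on GRCm38. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps. It was not stated whether the replicates were separate cultures, so each p-value measures the spread between these libraries, which could be technical only.

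The genes named were chosen by a rule. They are Ezh2, then up to 12 genes per direction with the largest change among those called, with a mean value of at least 50 and no overlap between groups, leaving out predicted models. Up to 4 members of smallest p were named from each gene list. Of 36 lists, 33 with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Each list was also tested with an estimated correlation and with fry, which tests whether a list's own genes move one way on balance. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries instead of the many genes. This weakens the test for every list, whether or not its genes are correlated. The median of the Polycomb target list was placed among 10000 random lists matched in 20 bins of mean expression. The lists, the naming rule, camera at the preset correlation and the comparison with matched random lists were fixed before the data were examined.

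The planned test was checked on simulated reads with 200 genes changed, 100 by 2-fold and 100 by 4-fold. The reads were turned into values by each gene's real ratio of deposited value to reads per library, or its median ratio where a library had 0 reads. The normalization was thus not redone. All genes had 1 dispersion (0.030), and GC and length trends of reads between libraries were not simulated. With changed genes of at least 10 reads on average among 17427 tested, the planned test recovered 0% of the 2-fold and 15% of the 4-fold changes, and 28 of its 43 calls were false. The same test limited to 11844 genes with at least 10 reads on average recovered 5% and 84%, with 2 of 91 calls false. A limma trend test of the recovered reads of those genes recovered 60% and 93%, with 6 of 159 calls false. With changed genes under 10 reads, the planned test recovered 1% and 4%, and 23 of 28 calls were false. In the simulated lists, camera called a list shifted by 0.7 (median found 0.63) and 0 of 30 unchanged lists. The simulated genes were drawn independently, so this cannot show how often camera calls a list because its genes are correlated.

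Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, the replicate block and each library left out. The filter of at least 10 reads on average, the fits on recovered reads, the removal of GC and length trends, the exclusion of the libraries in which 10 genes took the largest share, and the dropping of genes at 0 in all remaining libraries when 1 was left out were chosen after seeing the data. The lists of X-inactivation RNAs, mitochondrially encoded genes and small structured RNAs had too few genes in the table and were not analysed here.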

Results

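RNA levels were measured in mouse embryonic stem cells carrying floxed Ezh2, the gene for the catalytic subunit of Polycomb repressive complex 2 (PRC2). Untreated cells (n = 3 libraries) were compared with cells given 4-hydroxytamoxifen (n = 3) to delete it. The recovered reads came to 3855124, 5689666 and 2678212 in untreated replicates 1 to 3 and to 3849367, 2334448 and 5110226 in tamoxifen replicates 1 to 3. Between 10127 and 12686 genes had at least 10 reads in a library. The 10 most abundant genes took 22%, 25.3% and 36.7% of the reads in the untreated libraries and 32.3%, 20.2% and 23.1% in the tamoxifen libraries.

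Ezh2 itself was lower after tamoxifen but far from absent. Its normalized values were 4165, 3620 and 3483 in the untreated libraries and 2258, 2559 and 2609 in the tamoxifen libraries, on 181 to 694 recovered reads. The gene (ENSMUSG00000029687) lies on chromosome 6 from 47530139 to 47595341 on the minus strand of GRCm38. Mean Ezh2 was 3756 ± 361 in untreated and 2475 ± 190 in tamoxifen libraries (SD, n = 3), or 65.9% of the untreated level. The log2 fold change was -0.60 with a 95% interval from -0.88 to -0.32, and -0.40 on recovered reads (limma adjusted p 0.642). On deposited values the limma adjusted p was 0.195, so Ezh2 was not called, and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The values count the whole gene, and which exons are floxed is not stated, so reads from exons left in place count as Ezh2 too.

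The comparison of the 2 groups asks which RNAs differ after tamoxifen was given to delete Ezh2, a deletion that these values do not measure directly. Of the called genes with at least 10 reads on average, Plk2, Perp, Mdm2, Cald1, Tap1 and Clu rose and Cyp51 and Usp28 fell. Plk2, Perp, Mdm2 and Tap1 are targets of the tumour suppressor p53, and Cyp51 encodes an enzyme of cholesterol synthesis. In total 34 of 17427 genes were called by limma, 22 higher and 12 lower, and 1627 genes had an unadjusted p under 0.05. Genes whose 3 values in 1 group all lay above those of the other made up 15.3%, against 10% by chance. The difference between these shares was not tested, and genes measured in the same libraries are not independent.

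Plk2 (ENSMUSG00000021701, chromosome 13, 110395046 to 110400844) rose from 1358 ± 108 to 4703 ± 490 (SD, n = 3 per group), a log2 fold change of 1.79 ± 0.12 (SE) with limma adjusted p 0.00844. Perp (ENSMUSG00000019851, chromosome 10, 18845020 to 18857073) rose from 522 ± 83.8 to 2640 ± 397, a log2 fold change of 2.34 ± 0.18 with limma adjusted p 0.0102. Mdm2 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758) went from 1988 ± 287 to 5193 ± 370 and changed by 1.39 ± 0.14 on the log2 scale (limma adjusted p 0.0305). Cald1 (ENSMUSG00000029761), which encodes the actin-binding protein caldesmon, rose by 1.75 ± 0.16 on the log2 scale (limma adjusted p 0.0222). Tap1 (ENSMUSG00000037321), on 23.8 reads on average, rose by 1.45 ± 0.15 (limma adjusted p 0.0332). Clu, outside the naming rule and chosen after its values were seen, rose by 1.20 on the log2 scale with limma adjusted p 0.0440. Cyp51 (ENSMUSG00000001467, chromosome 5, 4081145 to 4104746) went from 4003 ± 318 to 1943 ± 121, a log2 fold change of -1.04 ± 0.11 (limma adjusted p 0.0349). Usp28 (ENSMUSG00000032267), a deubiquitinase gene, went from 3471 ± 73.4 to 1729 ± 161, a log2 fold change of -1.01 ± 0.11 (limma adjusted p 0.0351). Perp and Plk2 kept their calls with each library left out in turn. With 1 library left out, Cald1 (1.64 to 1.84) and Mdm2 (1.27 to 1.48) were called only without untreated replicate 2. Tap1 (1.39 to 1.48), Cyp51 (-1.09 to -0.98) and Usp28 (-1.08 to -0.94) were called in none of these fits.

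**Figure D1:**
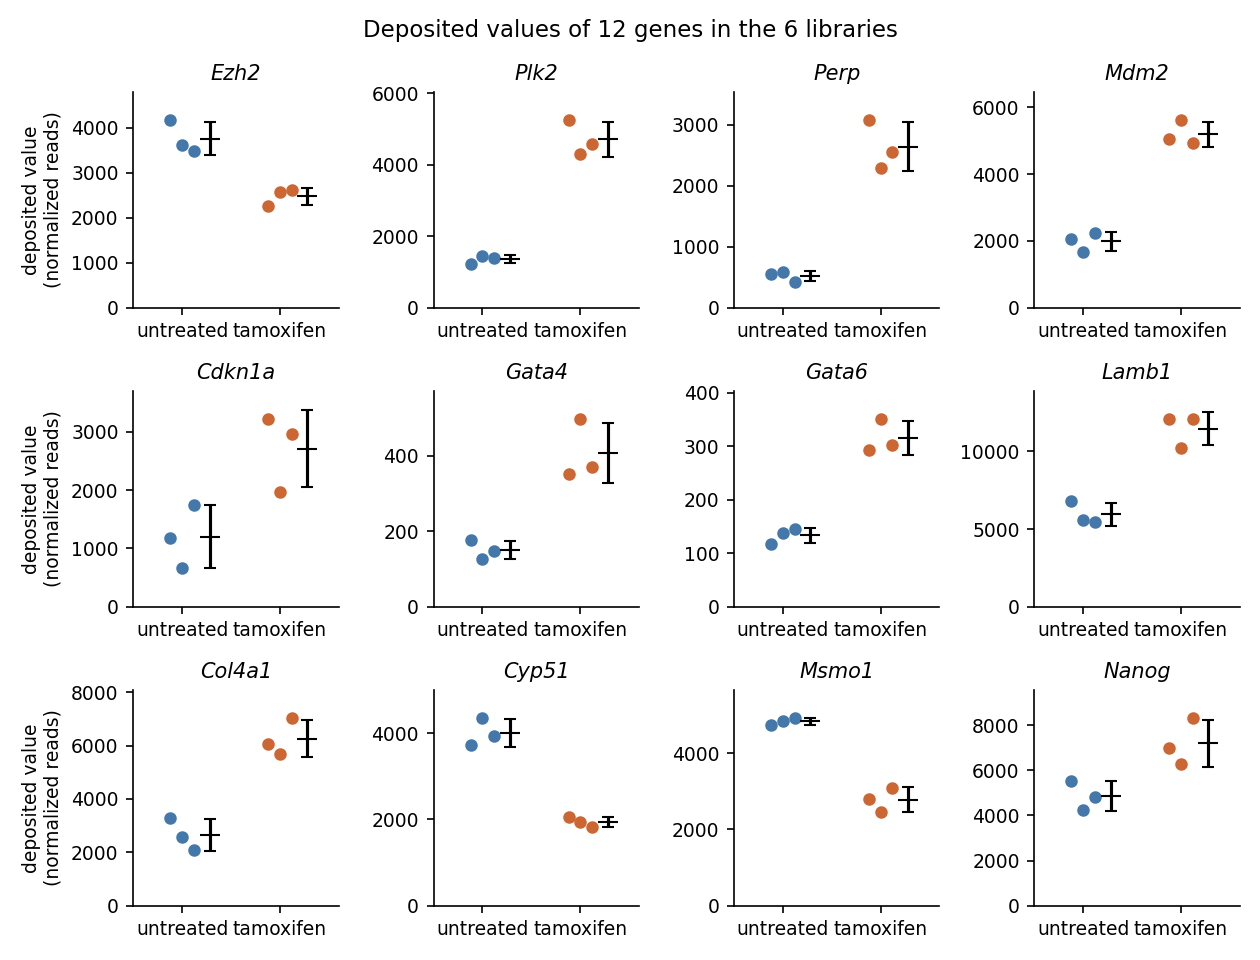
Deposited normalized values (vertical axis, linear, from 0) of 12 genes in the 3 untreated (blue) and 3 tamoxifen (orange) libraries, with points for libraries in replicate order and bars for the mean ± SD, the genes having been chosen after their values were seen. Mean Ezh2 was 3756 in untreated and 2475 in tamoxifen libraries, and Plk2 rose from 1358 to 4703.

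The other 26 called genes had under 10 reads per library on average, and such genes were 32.0% of those tested but 76.5% of those called. The developmental regulators Dlx3, Foxf2 and Wnt10b were among them, along with Adrb1, Tmem229a, Krt15 and Ugt1a1. All 7 had 0 reads in every untreated library. Dlx3 had 8, 6 and 6 reads in the tamoxifen libraries, at least 7.22-fold higher, and Tmem229a had 2, 5 and 6, at least 4.69-fold higher. Adrb1 had 1, 1 and 7 reads (at least 3.25-fold higher), Wnt10b 2, 2 and 4 (at least 2.89-fold) and Krt15 2, 1 and 3 (at least 2.17-fold). Foxf2 rested on 1, 2 and 2 reads (at least 1.80-fold higher) and Ugt1a1 on 1 read in each tamoxifen library, which gives no fold. In the other direction, Chadl had 6, 23 and 1 reads in the untreated libraries and 0 in the tamoxifen libraries, at least 9.24-fold lower, and Fgf21 had 4, 4 and 1 against 0, at least 2.77-fold lower. The remaining 17 were predicted models or had no symbol. The counting error of the reads above 0 is not part of these least folds, so the true folds could lie below them. The fold of Chadl rested mostly on untreated replicate 2 and that of Adrb1 mostly on tamoxifen replicate 3. Dlx3, Adrb1, Tmem229a, Wnt10b and Krt15 lost the call when any 1 tamoxifen library was left out, and Foxf2 when any 1 of the 6 was. Ugt1a1 kept it only without untreated replicate 2, Fgf21 lost it without untreated replicate 1 or 2, and Chadl kept it in all 6 cases. The highest limma adjusted p with 1 library left out was 0.0853 for Dlx3, 0.128 for Adrb1, 0.171 for Tmem229a, 0.216 for Foxf2, 0.23 for Wnt10b and 0.0626 for Fgf21. In the simulated data, 23 of 28 calls were false where the changed genes had under 10 reads on average.

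**Figure D2:**
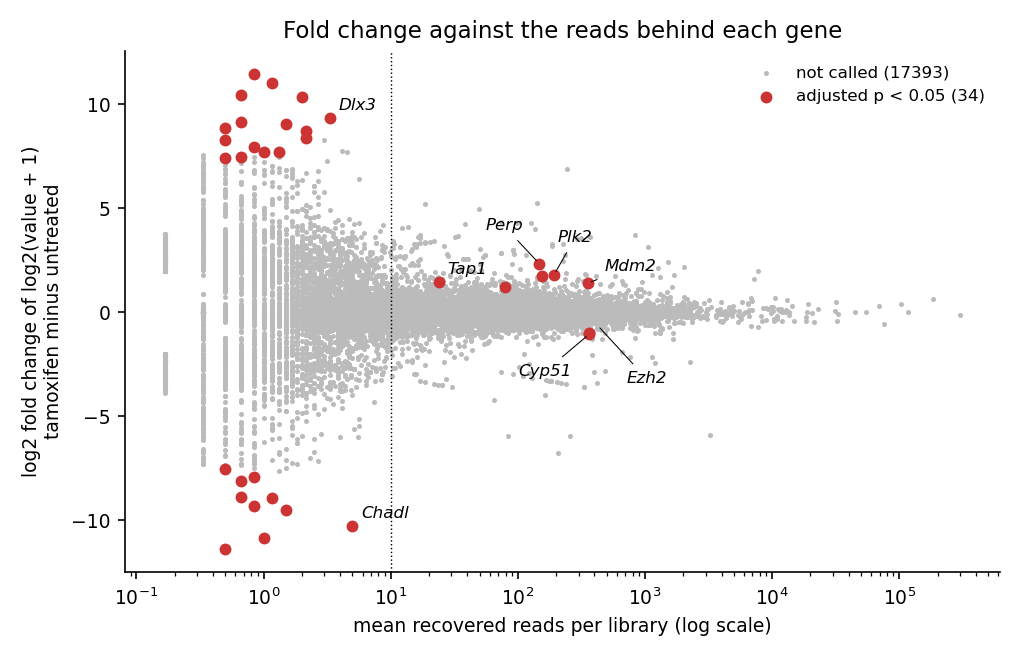
Log2 fold change of log2(value + 1), tamoxifen minus untreated, against mean recovered reads per library (log scale) for 17427 genes, with the 34 called genes in red and 10 reads marked by a dotted line. Of the called genes, 26 lie left of the line and 8 right of it.

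Limited to the 11843 genes with at least 10 reads on average, limma called 15 genes, 13 higher and 2 lower. The p53 targets Btg2 and Ccng1 and the genes Zfp365, Abcb1b, Wdr35, Gpx3 and Ercc5 joined the 8 above. Zfp365 rose by 2.34 on the log2 scale, Abcb1b by 1.52, Wdr35 by 1.51, Ercc5 by 1.53, Gpx3 by 1.45, Ccng1 by 1.37 and Btg2 by 1.26, with limma adjusted p between 0.0472 and 0.0485. These 7 were chosen after their values were seen. A limma trend test of the recovered reads called 5 genes, all higher, namely Plk2, Perp and Cald1 again with Pros1 and Ano3.

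Genes of primitive and visceral endoderm, the extraembryonic tissue that arises beside the epiblast, had the largest median rise among the called lists, while the mean was larger for trophoblast genes (1.502 against 1.475). The basement membrane genes Lamb1, Col4a2 and Col4a1 stood at 0.95, 1.27 and 1.27 on the log2 scale and Sparc at 0.75. The transcription factors Gata4 (1.43) and Gata6 (1.24), outside the naming rule, were chosen after their values were seen. The median of the 28 measured members was 1.09, and 26 were higher. Adjusted over the list alone 12 members were higher and 0 lower, against 0 over all genes tested. Of the 28, 5 are also in the Polycomb target list and 3 in the matrix and adhesion list. Camera gave the list an adjusted p of 2.04e-16, which became an adjusted p of 0.0769 with an estimated correlation, and fry gave 0.0170.

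The p53 targets were also higher. Plk2, Perp, Mdm2 and Tap1 led the 34 members, of which 29 were higher, with a median of 0.68. Adjusted over the list alone 22 were higher, Cdkn1a (1.25) and Ccng1 (1.37) included, and Rrm2b was lower (-0.75), against 18 higher and 0 lower on recovered reads. Over all genes tested 4 were higher. The camera adjusted p was 2.04e-16 and that of fry 0.00987. With an estimated correlation the call was lost, at an adjusted p of 0.0769 on deposited values and 0.126 on recovered reads.

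Cholesterol synthesis genes were lower. Cyp51 (-1.04), Msmo1 (-0.80), Fdft1 (-0.85) and Lss (-0.85) led 24 members, of which 23 were lower, with a median log2 fold change of -0.48. Adjusted over the list alone 9 were lower, and Cyp51 over all genes tested. Camera gave an adjusted p of 5.02e-14 (0.0769 with an estimated correlation) and fry 0.00987. Camera also called stress, glycolysis and S phase genes lower, but fry called none of these 3 lists (adjusted p 0.235, 0.281 and 0.226). The integrated stress response list had a median of -0.15 (camera adjusted p 0.00532, or 0.448 with an estimated correlation), with Trib3 (-0.73), Chac1 (-0.96) and Psat1 (-0.83) lower over the list alone and Mthfd2 at -0.53. Glycolysis and hypoxia genes had a median of -0.24 (camera adjusted p 0.00368, or 0.466 with an estimated correlation) with none past the threshold over the list alone, led by Pdk1 (-0.71), Mxi1 (-0.85), Gpi1 (-0.40) and Bnip3 (-1.63). S phase genes had a median of -0.11 (camera adjusted p 0.0470, or 0.436 with an estimated correlation), also with none past it, and Chaf1b (-0.48), Wdr76 (-0.31) and Tipin (-0.98) were among its lower members. The glycolysis list lost the call without tamoxifen replicate 2 (median -0.07, camera adjusted p 0.173) and the stress list without untreated replicate 1 (-0.05, 0.221). The S phase list lost it without untreated replicate 2 (-0.16, 0.117) or 3 (-0.10, 0.188) and without tamoxifen replicate 1 (-0.12, 0.215) or 3 (-0.17, 0.125), and over members with at least 10 reads on average (-0.10, 0.0590). On recovered reads camera called all 3 lists lower with larger medians, -0.32 for stress (adjusted p 2.11e-06, or 0.257 with an estimated correlation), -0.47 for glycolysis (7.13e-06, or 0.279) and -0.25 for S phase genes (0.000188, or 0.239). Fry again called none of the 3 there (adjusted p 0.110, 0.186 and 0.0909).

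Developmental regulators that Polycomb complexes are known to bind were higher on balance. Wnt10b and Foxf2 were called over all genes, on the few reads given above. Hand1 had 0, 1 and 0 reads in the untreated and 6, 8 and 10 in the tamoxifen libraries. Meis1, on 40.8 reads on average, rose by 2.56 on the log2 scale. Of the 81 measured members 50 were higher, and adjusted over the list alone 6 were higher (these 4 with Gata4 and Gata6) and 0 lower. The median was 0.32. It was 0.39 with the 14 members that had 1 group at 0 placed at their bounds, or left out where the other group had 3 reads or fewer. The median of 0.32 lay at percentile 99.8 of random lists matched in expression, of which 95% had medians between -0.15 and 0.21. Random lists do not measure the spread between libraries. Of the 10 splits of the 6 libraries into groups of 3, 3 lay at least as far from percentile 50, the real one included. Without the 5 members shared with the endoderm list the median was 0.26, at percentile 97.9. Camera gave an adjusted p of 0.0108 and fry 0.00987. Only 21 of the 81 members reached 10 reads on average, with adjusted p of 0.00142 by camera and 0.00827 by fry. The fry adjusted p was 0.0547 on recovered reads. The camera call was lost with an estimated correlation (adjusted p 0.165), on ranks (adjusted p 0.0667) and without tamoxifen replicate 1 (adjusted p 0.102, median 0.19).

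Hox genes, another group under Polycomb control, showed no call at this depth. The 22 measured genes had a fitted median of -0.61 (camera adjusted p 0.823). The median was 0.07 with members that had 1 group at 0 placed at their bounds, or left out where the other group had 3 reads or fewer. Only 3 of the 22 genes reached 10 reads on average. Hoxa3 rose by 1.29 and Hoxb13 by 0.49 on the log2 scale, neither called, while Hoxc4 and Hoxd1 had 1 read in each of 2 untreated libraries and 0 elsewhere.

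The partners of Ezh2 did not move together. The 12 other PRC2 genes had a median of -0.06 (camera adjusted p 0.731), which was 0.00 over the 11 with at least 10 reads on average. Aebp2 changed by 0.65, the paralogue Ezh1 by -0.64, Rbbp7 by -0.36 and Epop by 0.22 on the log2 scale, none past the threshold over the list alone. PRC1 genes had a median of 0.27 (camera adjusted p 0.203), led by Pcgf3 (0.51), Bmi1 (0.70), Pcgf6 (-0.43) and Phc2 (0.64). The H3K27 and H3K4 methylation list, which mixes genes of methylating and demethylating enzymes, had a median of -0.12 (camera adjusted p 0.159). It was led by the demethylase genes Kdm6a (-0.42), Kdm5d (-0.45) and Kdm5b (-0.49) and by Kmt2e (-0.46). Kdm6a stood at -0.07 and Kmt2e at -0.09 on recovered reads. That list was called lower without untreated replicate 2 (median -0.15, camera adjusted p 0.0456) or tamoxifen replicate 2 (-0.11, 0.035), and on recovered reads with GC and length trends removed (-0.20, 0.00678). In that last fit the call was lost with an estimated correlation (adjusted p 0.183) and fry gave 0.0849.

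Pluripotency genes went both ways, with a median of -0.0050 over 37 members that changed sign with trimmed-mean scaling (camera adjusted p 0.823). Adjusted over the list alone Tfcp2l1 (0.70) and Tbx3 (0.89) were higher and Dppa4 (-0.54) was lower, and Nanog stood at 0.57. On recovered reads the list's median was -0.14 and 0 members passed the threshold over the list alone. The formative and primed epiblast list had a median of -0.31 and a mean of 0.21 (camera adjusted p 0.382). Camera called it lower over members with at least 10 reads on average (median -0.42, adjusted p 0.0235, or 0.303 with an estimated correlation), on recovered reads (-0.38, adjusted p 0.00196, or 0.139 with an estimated correlation) and with GC and length trends removed (-0.43, adjusted p 0.00346, or 0.134 with an estimated correlation). Fry gave 0.131, 0.0320 and 0.0313 there. Its members Cldn6, Sox12 and Pim2 stood at 0.62, -0.45 and -0.51, and Wnt8a, higher over the list alone, rested on 1, 2 and 1 reads against 2, 2 and 5. Neural genes had a median of 0.07, a mean of -0.17 and a lower direction by camera (adjusted p 0.203), and the median became -0.09 with quantile normalization. Adjusted over that list alone Crmp1 (-1.52) and Stmn2 (-0.47) were lower, as was Hes5 on 1, 1 and 1 reads against 0, 0 and 1, and Nefl was higher on 1, 1 and 0 reads against 1, 11 and 2.

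The other called lists were higher, each with 0 members called over all genes tested, and each lost the call with an estimated correlation. Of these, fry did not call the fibroblast (adjusted p 0.0699), mesendoderm (0.131) and retinoic acid (0.281) lists. All 23 trophoblast genes were higher, with a median of 0.70 (camera adjusted p 6.40e-09, or 0.0769 with an estimated correlation), Hand1 past the threshold over the list alone, and Krt18 (0.89), Id2 (0.77) and Ets2 (0.57) next. Fibroblast genes had a median of 0.60 (adjusted p 3.37e-05, or 0.314 with an estimated correlation), with Ccn1 (0.82), S100a6 (0.83) and Postn (0 reads against 1, 2 and 2) higher over the list alone and Fn1 at 0.74. Matrix and adhesion genes had a median of 0.28 (adjusted p 1.45e-05, or 0.0769 with an estimated correlation), and Col4a2, Col4a1, Sparc and Krt18 were higher over the list alone (2 members on recovered reads, with a median of 0.18). Mesendoderm genes had a median of 0.42 (adjusted p 0.00623, or 0.363 with an estimated correlation), with Hand1 and Pdgfra (1.33) higher over the list alone, Lefty2 at 0.61 and Wnt3 on 2, 4 and 1 reads against 6, 11 and 11. TGF-beta and BMP targets had a median of 0.33 (adjusted p 0.00242, or 0.133 with an estimated correlation), with Id1 (0.86), Pmepa1 (1.13) and Dusp9 (0.57) higher over the list alone. Immediate early genes had a median of 0.17 (adjusted p 0.00827, or 0.133 with an estimated correlation), with Btg2 higher over the list alone and Csrnp1 (0.46), Klf6 (0.55) and Nr4a1 (0.26) next. On recovered reads the median of that list was 0.08 and the call was lost (camera adjusted p 0.358), as it was with GC and length trends removed (0.13, 0.0807). Retinoic acid response genes had a median of 0.60 (adjusted p 0.0298, or 0.448 with an estimated correlation), with Meis1 higher and Crabp1 (-0.66) lower over the list alone, and Meis2 (1.72) and Tgm2 (0.69) next. That list lost the call without untreated replicate 3 (median 0.27, camera adjusted p 0.149) and without tamoxifen replicate 2 (0.65, 0.0891) or 3 (0.63, 0.0587), and over members with at least 10 reads on average (0.66, 0.0512).

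**Figure D3:**
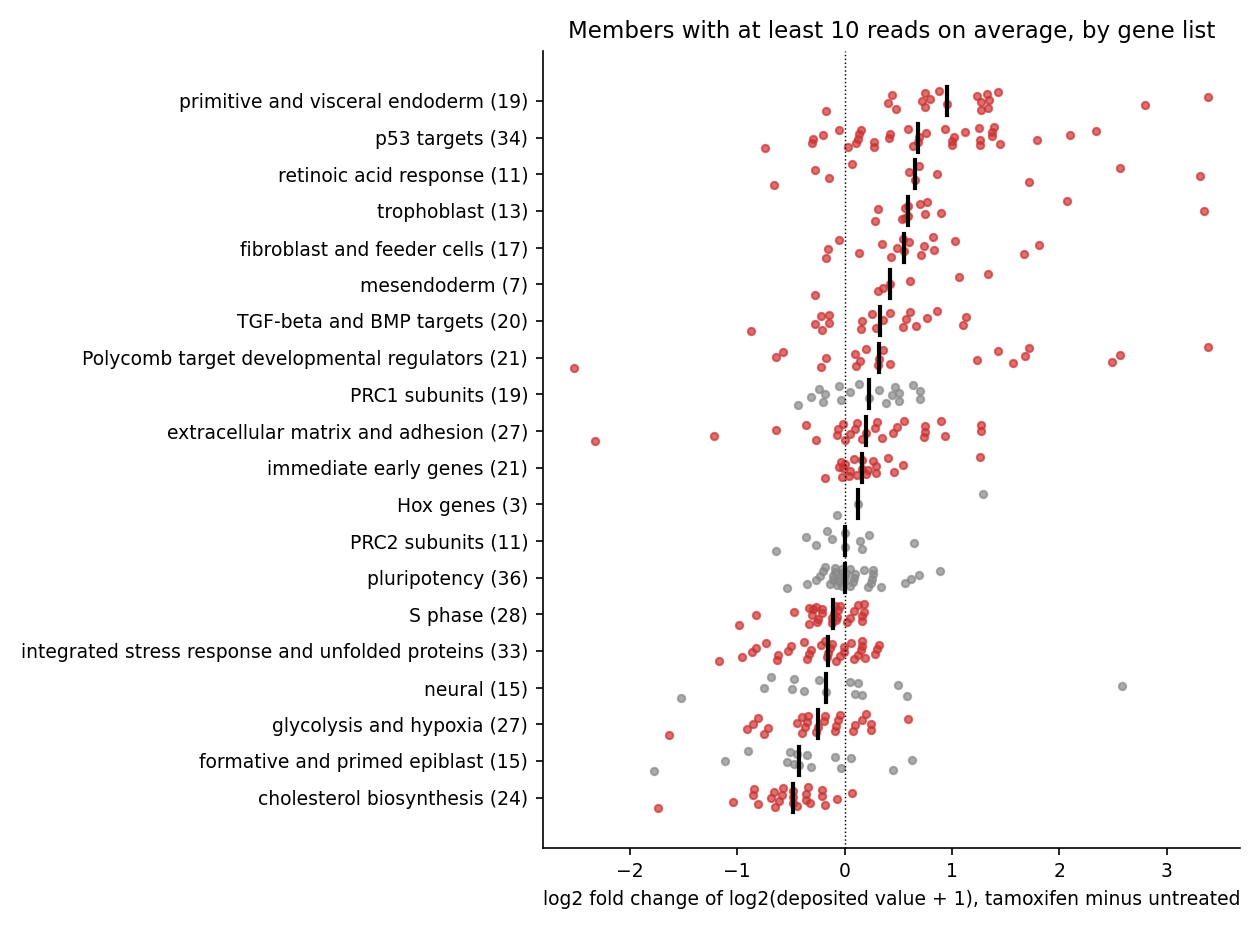
Log2 fold changes, tamoxifen minus untreated, of the members with at least 10 reads on average (points) in 20 gene lists, with the median as a black bar, the number of members in brackets, and red for lists that camera called over all their measured members. Medians run from -0.48 for cholesterol biosynthesis to 0.95 for primitive and visceral endoderm.

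The remaining lists were not called by camera, with adjusted p from 0.267 for G2 and M phase genes to 0.987 for ribosomal proteins. Medians were 0.00 for G2 and M phase (Kif2c -0.44, Aurkb -0.30, Ccnb1 -0.27, Cdca8 -0.20), 0.05 for WNT targets (Dkk1 1.19, Lef1 -1.78, Cdx1 1.07, Znrf3 0.88) and 0.12 for imprinted genes (Sfmbt2 0.89, Plagl1 2.01, Igf2r 0.56, Phlda2 -0.31). On recovered reads the G2 and M phase median was -0.15 and camera called that list lower (adjusted p 0.0109, or 0.279 with an estimated correlation). Interferon response genes had a median of 0.22, with Tap1 called, Stat2 at -0.79 and Zbp1 and Oas1b on at most 5 reads per library. The median was -0.20 over members with at least 10 reads on average (9 of 14 lower) and -0.38 on recovered reads (10 of 14 lower), with no call by camera. Germline genes had a median of -0.01 (Tex11 -0.94, Mael -0.85, Tex13b 0.82, Zcwpw1 -0.84) and cyclin-dependent kinase inhibitors 0.25 (Cdkn1a 1.25, Cdkn1c -0.24, Cdkn1b -0.25, Cdkn2c -0.50). DNA methylation enzymes had 0.03 (Mbd1 0.37, Dnmt3a -0.47, Uhrf1 -0.26), heat shock genes -0.06 (Ahsa1 -0.29, Hsph1 0.40, Bag3 0.61, Hspe1 -0.22) and oestrogen receptor targets 0.11 (Ctsd 1.08, Esr1 -1.59, Myb -1.30, and Ltf on at most 3 reads per library). On recovered reads Ctsd stood at 0.20 and Esr1 at -0.70. The next families have nearly identical copies, and their values are uncertain for that reason. Histone genes had a median of -0.00 (Hist1h4n -0.45, Hist1h3e -0.87, Hist1h2bj 0.77, Hist1h2aa 0.33) and ribosomal protein genes -0.02 (Rpl35a 0.27, Rps27a 0.19, and Rpl13 on at most 2 reads per library). On recovered reads camera called both lower, with medians of -0.64 for histones (adjusted p 5.08e-09, or 0.498 with an estimated correlation) and -0.33 for ribosomal proteins (2.11e-06, or 0.453), and fry called neither (0.470 and 0.303). The 2-cell-like list had -0.00, led by Zscan4f, Gm2016, BC080695 and Sp110, each on at most 6 reads per library. The median became positive with trimmed-mean scaling for the germline, histone and 2-cell-like lists. Median and mean differed in sign for G2 and M phase, DNA methylation, heat shock, ribosomal protein, 2-cell-like and pluripotency genes.

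The log2 fold changes of several other list members named here moved by over 1.5 times on recovered reads. Hist1h2bj turned from 0.77 to -0.39. Smaller changes were found for Aebp2 (0.41), Ezh1 (-0.40), Rrm2b (-0.37), Mxi1 (-0.45), Tipin (-0.61), Sparc (0.48), Csrnp1 (0.28), Dusp9 (0.33), Nanog (0.35), Stmn2 (-0.30), Lef1 (-0.92), Tex11 (-0.51) and Hsph1 (0.14). Larger ones were found for Id1 (1.36), Id2 (1.76), Bmi1 (1.37), Epop (0.38), S100a6 (1.35), Mthfd2 (-0.90), Sox12 (-0.98), Pim2 (-0.93), Crabp1 (-1.05), Cdkn1c (-0.64), Phlda2 (-0.74), Tex13b (1.44), Hist1h4n (-0.88), Hist1h2aa (0.69), Aurkb (-0.53), Cdca8 (-0.34), Hspe1 (-0.37), Ahsa1 (-0.44) and Uhrf1 (-0.40).

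In all, camera called 14 of 33 lists, 10 higher and 4 lower. With an estimated correlation 0 were called, the lowest adjusted p being 0.0769, shared by the endoderm, p53, cholesterol, trophoblast and matrix lists, and 8 had an unadjusted p under 0.05. The matrix and immediate early lists lost the call although their estimated correlations, -0.013 and -0.024, lay below the preset 0.01. A call lost in this test is therefore not by itself a sign of correlated genes. Fry called 9 lists, 8 of them also called by camera and the other the interferon response list (higher, adjusted p 0.0463). Over members with at least 10 reads on average fry called 7 lists and the interferon call was lost (adjusted p 0.952), as it was on recovered reads (0.691).

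Correlations between libraries of the 2 groups overlapped those within a group. Pearson correlations of log2(value + 1) across genes were 0.782 to 0.788 within the untreated group, 0.782 to 0.797 within the tamoxifen group and 0.769 to 0.795 between groups. Principal component 1 of the 2000 most variable genes held 23.3% of the variance, with the tamoxifen libraries at 25.1 to 70.1 and the untreated ones at -8.00, 19.8 and -172.8, replicate 3 lying farthest out, and component 2 held 21%. On recovered reads component 1 held 29.2% and placed untreated replicates 2 and 3 (33.8 or above) apart from untreated replicate 1 (-12.8) and the tamoxifen libraries (-27.8 to -11.4). Untreated replicate 3 also had the largest share of reads in 10 genes, 36.7%.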

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

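The fits on recovered reads or on genes with at least 10 reads, the removal of GC and length trends, the exclusion of libraries and the dropping of genes at 0 in all remaining libraries were chosen after seeing the data. Against 34 genes called, limma called 52 with a pseudocount of 8 and 52 without a filter. Without the expression trend it called 62. It called 15 among genes with at least 10 reads, 8 of them shared with the 34. On recovered reads it called 5 with a trend, 3 with voom and 22 with the GC and length trends removed. It called 0 on genes with at least 10 reads without the library of each group in which 10 genes took most reads (917 at an unadjusted p under 0.05). The cause was not tested, apart from the smaller number of genes or libraries that some of these settings use. Leaving out each library in turn gave 32 to 56 genes, of which 27.5% to 87.5% were higher, against 64.7% in the full set. The highest count, 56, came without untreated replicate 2. Scaling moved neither count nor split by that much, with 34 to 44 genes called and 63.6% to 65.7% higher.

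Replicate numbers showed no sign of pairing the libraries, though low correlations of noisy values cannot exclude it. Same-numbered deviations correlated at -0.00, -0.02 and -0.04 on deposited values and at -0.09, -0.06 and 0.08 on recovered reads. Differently numbered ones ran from -0.01 to 0.04 on deposited values and from -0.17 to 0.20 on recovered reads. With the replicate block limma called 0 genes on deposited values (1393 at an unadjusted p under 0.05, lowest adjusted p 0.180) and 0 on recovered reads (929, 0.0534), and 14 lists.

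Ezh2 kept its direction and stayed uncalled in all 23 alternatives (log2 fold change -0.65 to -0.40, limma adjusted p 0.157 to 0.715). Camera called 12 to 14 lists with each library left out. It called 0 with an estimated correlation, whether on all genes, on those with at least 10 reads or on recovered reads. Fry called 9 on all genes and 7 on those with at least 10 reads, and on recovered reads it called the endoderm, p53, cholesterol and formative lists. For the Polycomb target list the estimated correlation gave an adjusted p of 0.165, 0.0877 and 0.140 with medians of 0.32, 0.32 and 0.30, ranks gave 0.0667 (median 0.32), and leaving out each library gave medians of 0.19 to 0.62. The adjusted p ran from 0.000396 to 0.165 over all 24 alternatives, and the percentile from 98.3 to 99.9 over 5. The cause was not tested.

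Ribosomal protein genes, with a median of -0.02 and an upward direction by camera in the planned test, were called lower by camera on recovered reads, with medians of -0.33 with a trend, -0.33 with the replicate block, -0.35 with voom and -0.14 with GC and length trends removed. With a trend neither fry (adjusted p 0.303) nor an estimated correlation (adjusted p 0.453) called them. Camera also called histone (median -0.64), G2 and M phase (-0.15) and formative (-0.38) genes lower there, with adjusted p of 0.498, 0.279 and 0.139 with an estimated correlation. The cause was not tested. The planned edgeR and DESeq2 alternatives were not run, since the deposited table holds a normalized signal. At 2334448 to 5689666 reads per library, 5584 of the genes tested had under 10 reads on average, and the planned test recovered 15% of simulated 4-fold changes above that level.

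The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split called 34 genes and the highest other 29, 15 against 4 among genes with at least 10 reads, and 14 lists against 7, so 1 split, the real one, reached each count. The Polycomb list's percentile lay 49.8 from 50, against up to 50 in other splits, and 3 splits lay as far.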

Other observations

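The tests in this part were chosen after the results were seen. Most called genes rest on few reads, 26 of 34 under 10 on average. Splits of the libraries other than the real one called a median of 12 such genes and up to 25, so the spread that the deposited values give to genes of few reads is a candidate explanation for many of these calls.

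Plk2, Perp, Mdm2 and 26 others of the 34 p53 targets were higher after tamoxifen, 22 of them past the threshold adjusted over the list alone and 4 over all genes tested. With the GC and length trends removed the list's median was 0.69 (fry adjusted p 0.0128, camera adjusted p 0.102 with an estimated correlation), which argues against those trends as the whole cause. With 1 library left out it stayed between 0.62 and 0.81, which argues against a single library, although fry gave 0.0559 without tamoxifen replicate 3. Whether the rise may come from tamoxifen or the recombinase apart from the loss of Ezh2 cannot be told apart, since 0 libraries had tamoxifen without floxed Ezh2. An effect of Ezh2 loss itself also stays open.

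Gata4, Gata6, Col4a1 and other endoderm genes were higher, with a median of 1.01 after removal of GC and length trends (fry adjusted p 0.0128, camera adjusted p 0.102 with an estimated correlation) and 0.82 to 1.21 with 1 library left out, which argues against either as the whole cause. Fry gave 0.0558, 0.0624 and 0.0925 without tamoxifen replicates 1, 2 and 3. Over members with at least 10 reads the endoderm median exceeded the neural one by 1.12 (95% interval 0.65 to 1.72, permutation p 0.00112 over genes). Genes of a list are not independent (estimated correlation 0.142 for the endoderm list), so the interval is too narrow and the p too small. The neural list was also picked for this after its values were seen. The difference shows only that these neural genes did not rise like the endoderm genes. It cannot decide whether differentiated cells of every kind rose alike, and camera called the trophoblast, mesendoderm and fibroblast lists higher too. Fry did not call the mesendoderm (adjusted p 0.131) or fibroblast (0.0699) list. The mesendoderm list shares Foxa2 and Pdgfra with the endoderm list and Cdx2, Eomes and Hand1 with the trophoblast list. More cells of an endoderm kind remain a candidate explanation, with 18 of 19 endoderm members of at least 10 reads higher. Lamb1 and Sparc were already at 5949 and 4843 in untreated cells. Such a rise in cells cannot be told apart from a change within each cell in RNA from whole cultures. Loss of Ezh2 and tamoxifen itself both stay open.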
